A study of Capra hircus and Bos taurus with 7 samples.

How the data were processed

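Small RNA was measured by sequencing in extracellular vesicles isolated from 7 reconstituted milk powder samples. Per the labels' protocols, vesicles were isolated by size exclusion chromatography, RNA was extracted with a kit for total RNA including small RNA, libraries were made with a small RNA kit and size-selected on acrylamide gel, and single-end reads of 50 bases were sequenced. The goat libraries were grouped by their titles into whole and skimmed powder (3 each), and the single bovine library stood alone. Per the file headers, each deposited table gives counts per mature miRNA, for the same 364 bovine miRNA names in every library. Since many values are fractions they were read as estimated counts, and the deposited estimated counts were taken as not normalized, since library totals ranged from 5675489 to 11963849 reads. Between 36.9% and 46.7% of the values above 0 were whole numbers (within 1e-06), and the fractions are of the kind left when a read matching several entries is divided between them. The aligner, the counter, the miRNA reference version and the genome build are not given in the sources used here. Goat reads were thus named by bovine miRNAs, and how goat reads that differ from the bovine sequences were treated is not given in the sources used here. A table of goat genes supplied without the deposited data was not used, because the build behind the counts is not known, and no coordinates are given.

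Values in CPM were computed here as counts-per-million, over the estimated counts of all 364 miRNAs of a library. For tests the estimated counts were rounded to whole numbers. The main comparison, skimmed against whole goat powder, used edgeR 4.0.16 in R 4.3.3 on the 6 goat libraries, with the default filter on low counts (209 miRNAs kept), TMM scaling (factors 0.928 to 1.067), the quasi-likelihood test and Benjamini-Hochberg adjustment, at an adjusted p of 0.05. The SE of a log2 fold change is its size divided by the square root of the test's F value. No design with shared spread over the bovine library was used, and the bovine library was described by its fold against the goat mean and range, with exact Poisson intervals at 95% for its CPM and exact Clopper-Pearson binomial intervals for its shares. PCR reads without molecular identifiers are not independent molecules, so these intervals and floors cover counting error only. Group differences in single values used exact two-sided permutation tests over 3 against 3 libraries, which cannot give a p below 0.1. Thinned numbers of miRNAs are the expected numbers at the total of the smallest goat library.

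A set of 11 miRNA lists was fixed before the data were examined: miRNAs often reported in milk vesicles, epithelial, lipid metabolism, leukocyte, erythroid, stromal and endothelial, and muscle, liver and nerve miRNAs, the let-7 and miR-98 family, the miR-30 family, the miR-17-92 cluster with its paralogs, and the DLK1-DIO3 imprinted cluster. Members were matched by name without the species prefix, counting each arm, and lists overlap in members. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry (limma 3.58.1, edgeR 4.0.16); fry tests whether the members of a list move on balance one way, or in its mixed form in either direction, and does not compare a list with other miRNAs. The read shares of the lists with their permutation tests, and the use of fry's mixed form as a result, with its adjustment over the lists, were added after the data were examined. Giving miR-381, the 1 tested miRNA at 0 in all skimmed libraries, its bound in place of its fitted value moved the median of 0 lists.

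The miRNAs named were set by a rule fixed at the same time: the 10 with the highest mean CPM in goat; those past the threshold and, as fewer than 10 passed, the 5 with the lowest p in each direction; the 3 most abundant tested members of each list; and for the bovine library its 10 highest and the 5 farthest above and below the goat range among those with a mean of at least 100 CPM. Other miRNAs are named as members of a count of a list, as the lead of a share, or as stated.

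The 6 pairs of libraries within a powder differed far beyond sampling noise (chi-square per degree of freedom 507 to 1670), so no library was a copy of another. No label gives a batch. The fits were tested on simulated data first, with counts drawn for the 209 miRNAs from the means, library sizes and spread of the skimmed and whole libraries and 40 miRNAs changed in each of 20 simulations. A 4-fold change was recovered for 99.2% of changed miRNAs with at least 1000 CPM and for 18.2% of those below, a 2-fold change for 74.4% and 3.2%, and 2.9% of calls fell on unchanged miRNAs. Each miRNA was drawn from a single smooth distribution, not made to copy low miRNAs that are high in some libraries and near absent in others. Recovery and wrong calls among low miRNAs may therefore differ in the data. A 2-fold shift of the let-7 and miR-98 family was recovered by camera at the preset correlation in 20 of 20 simulations. The simulated miRNAs were drawn independently, while the estimated correlation of this list in the data was 0.23. The recovery therefore does not measure the power for members that move together. Alternatives to the scaling, the filter, the depth, the tool, the threshold, the block and the set of libraries were run, among them DESeq2 1.42.0 and limma-voom. Summing 8 pairs of rows that share reads, and dividing reads by an estimate of the reads per template molecule, were alternatives chosen after seeing the data.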

Results

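Small RNAs carried by extracellular vesicles (EVs), the membrane-bound particles that cells release, were profiled in reconstituted milk powders. The vesicles had been separated by size exclusion chromatography. The 7 small RNA libraries comprised 3 from whole goat milk powder, 3 from skimmed goat milk powder and 1 from a commercial bovine powder. The libraries of each goat powder carry the letters A to C. Nothing in the labels says whether the letters stand for separate packs, batches or repeat isolations of 1 powder, so the p-values measure only the spread between these libraries, which may be technical. Each library held estimated reads for the same 364 mature microRNAs (miRNAs), all under bovine names. The whole-milk libraries held 6561887, 10143033 and 11963849 miRNA reads, the skimmed-milk libraries 9285189, 8284937 and 7953807, and the bovine library 5675489. Genomic positions are not given here, because the genome build behind the deposited names is not given in the sources used here.

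The vesicles of both goat powders carried a miRNA population led by the let-7 family, whose members are conserved repressors of growth-related mRNAs. By mean over the 6 goat libraries the most abundant miRNA was let-7a-5p, at 117668 ± 13203 counts-per-million (CPM; SD, n = 3) in whole and 143485 ± 13674 CPM (SD, n = 3) in skimmed powder. It was followed in that mean by let-7f, at 64291 ± 3564 CPM in whole and 71398 ± 2489 CPM in skimmed, and by miR-21-5p, at 66912 ± 6311 and 51906 ± 9773 CPM. The next places in that mean were held by miR-30a-5p, which at 72635 ± 9541 CPM stood above let-7f and miR-21-5p in whole powder, and by miR-30d, miR-148a (a miRNA long known to be abundant in milk), let-7b, miR-148d, miR-200c (a member of the epithelial miR-200 family) and miR-26a. Of these, miR-148a stood at 51332 ± 11554 CPM in whole and 53245 ± 9007 CPM in skimmed, and miR-200c at 34336 ± 566 and 40434 ± 3549 CPM. The rows of miR-148a and miR-148d moved together in all libraries, with a log2 ratio between 0.13 and 0.22, as did those of miR-26a and miR-26c, with a log2 ratio of 1.00 throughout. Both are pairs of near-identical names whose reads the deposited counting could split, so the values of their members are uncertain.

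**Figure D1:**
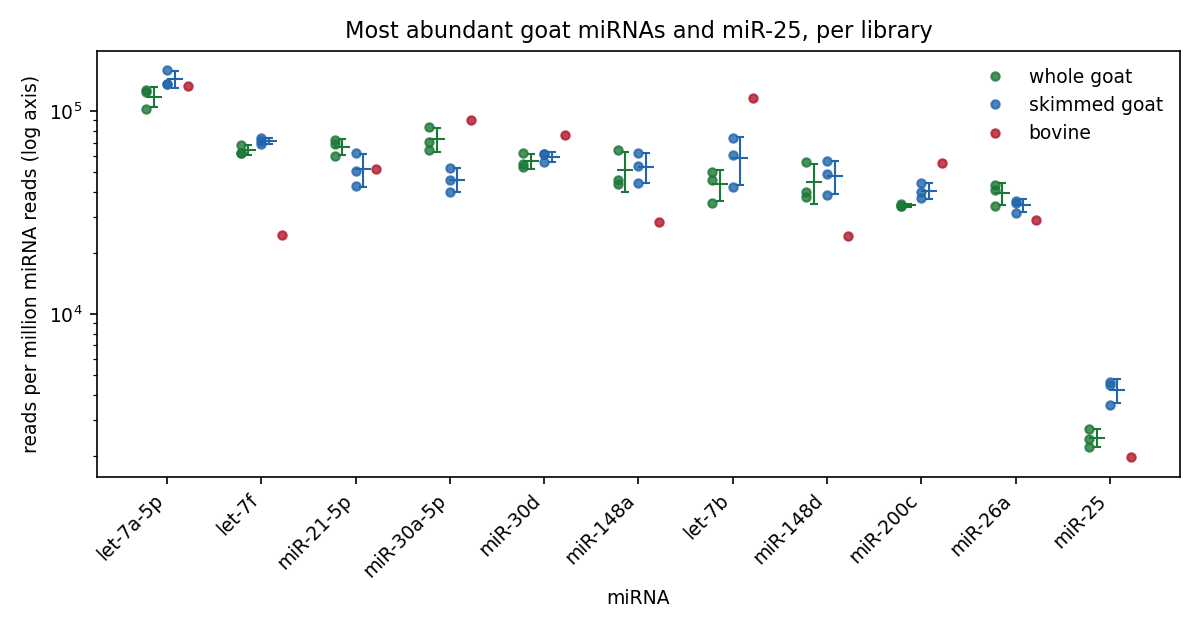
CPM (log axis) of the 10 most abundant goat miRNAs and of miR-25 in each library; points are libraries, and dashes with bars are the mean ± SD of the 3 libraries of a goat powder. The 3 skimmed libraries lay between 3557 and 4600 CPM for miR-25 and the 3 whole libraries between 2219 and 2715 CPM.

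The 10 leading miRNAs took 59.2% ± 1.72 (SD, n = 3) of the miRNA reads of whole powder and 60.7% ± 0.267 (SD, n = 3) of those of skimmed powder. The difference of 1.59 percentage points did not pass an exact two-sided permutation test (p = 0.2), for which 3 libraries against 3 allow no p below 0.1. A total of 148 miRNAs had at least 10 reads in every goat library, and these held at least 99.7% of the reads of each. In whole powder 253 ± 5.13 miRNAs had at least 1 read, and in skimmed powder 249 ± 8.54 (SD, n = 3 each). At the depth of the smallest goat library the numbers were 245 ± 8.50 and 243 ± 6.69 (exact permutation p = 0.7). The sign of this difference turned when whole library A or skimmed library B was left out, with skimmed then higher by 2.18 and by 0.97 miRNAs. Across 214 miRNAs with a mean of at least 10 CPM, the rank correlation of goat libraries averaged 0.920 between libraries of whole powder, 0.917 between libraries of skimmed powder and 0.912 between the powders. These are correlations across miRNAs, which are not independent replicates.

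The next comparison set powder labelled skimmed against powder labelled whole. Nothing in the labels says that the powders came from the same milk or lot. Removal of fat therefore cannot be told apart from other differences between the powders. One named miRNA, miR-25, rose in skimmed powder. This member of the miR-106b-25 cluster stood at 2456 ± 248 CPM in whole and 4214 ± 572 CPM in skimmed powder (SD, n = 3), a 1.82-fold difference with a log2 fold change of 0.87 ± 0.13 (SE) and an adjusted p of 0.035 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 209 miRNAs. All 3 skimmed libraries lay above all 3 whole libraries. Its cluster partners did not pass the threshold, at a log2 fold change of -0.07 ± 0.41 (SE) for miR-93 and -0.38 ± 0.65 for miR-106b, with adjusted p of 0.97 and 0.96 in edgeR; miR-106b was named after its value was seen. No miRNA fell past the threshold in edgeR. DESeq2's Wald test called 22 miRNAs, 10 higher and 12 lower in skimmed, and limma-voom called 1. Of DESeq2's calls, 13 were all-or-none miRNAs, with at least 100 reads in one goat library and at most 10 in another. The other 9 were miR-25, miR-30b-5p, miR-30c, miR-151-3p and let-7a-5p higher and miR-885, miR-30a-5p, miR-125a and miR-125b lower in skimmed. At an unadjusted p under 0.05 in edgeR there were 22 miRNAs, 12 higher and 10 lower in skimmed, where 10.5 are expected by chance. Skimmed and whole libraries did not overlap for 42 of the 209 miRNAs, or 20.1%, against the 10% that chance gives on average for 3 against 3. Overlap was scored on CPM without TMM scaling. The miRNAs of a library are not independent, so a single split can depart from that average without a difference between powders. The share in other splits is not given here. The miR-25 call was lost when any 1 of whole A, whole B, whole C, skimmed B or skimmed C was left out (edgeR adjusted p 0.072, 0.16, 0.082, 0.24 and 0.12), with a log2 fold change of 0.81 to 0.94 over all 6 such fits. It was also lost with DESeq2 size factors (0.058), library totals (0.059), upper-quartile scaling (0.075) or let-7a-5p left out (0.057), and over all alternatives the adjusted p ranged from 0.00011 to 0.24.

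Next after miR-25 came miRNAs that did not pass the threshold over all miRNAs in edgeR. Of the more abundant ones named here, DESeq2's Wald test called 5, miR-885 (adjusted p = 0.00064), miR-30a-5p (0.0032), miR-30b-5p (0.0062), miR-30c (0.025) and miR-151-3p (0.045). It did not call miR-223 or miR-141, and it also called the low miR-381 and miR-296-3p, given below. Values above 0 were led by miR-30b-5p, at 1566 ± 141 CPM in whole and 2490 ± 339 CPM in skimmed (log2 fold change 0.76 ± 0.15 SE, edgeR adjusted p = 0.076). Behind it stood miR-223, a miRNA of myeloid cells, at 1174 ± 32.2 and 1610 ± 110 CPM, miR-151-3p at 3034 ± 71.7 and 3912 ± 321 CPM, and miR-30c at 4779 ± 648 and 6621 ± 956 CPM, each with an edgeR adjusted p of 0.12. Below 0 the first was miR-885, at 4650 ± 849 CPM in whole and 2630 ± 175 CPM in skimmed (log2 fold change -0.72 ± 0.15 SE, edgeR adjusted p = 0.076). The abundant miR-30a-5p stood at 72635 ± 9541 and 46018 ± 6230 CPM, with a log2 fold change of -0.57 ± 0.15 (SE), and the epithelial miR-141 at 2386 ± 99.2 and 1542 ± 304 CPM, both with an edgeR adjusted p of 0.12. At the low end, miR-381 had 376, 178 and 320 reads in the whole libraries and 0 in each skimmed library. The ratio was 259 against a floor of 3 reads over the skimmed group, and at least 210 by the lower limit of its exact 95% Poisson interval. Likewise miR-296-3p had 145, 778 and 249 reads in whole and 0, 1 and 1 in skimmed, a pooled ratio of 522 (95% interval 144 to 4313, exact for Poisson counts). Its ratio against the floor of 3 reads was 348, and most of its whole reads were in whole B. Neither passed the threshold in edgeR (adjusted p = 0.12), while DESeq2's Wald test called both as lower in skimmed (adjusted p = 0.00012 for miR-381 and 0.00011 for miR-296-3p). Such intervals and floors cover counting error only.

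**Figure D2:**
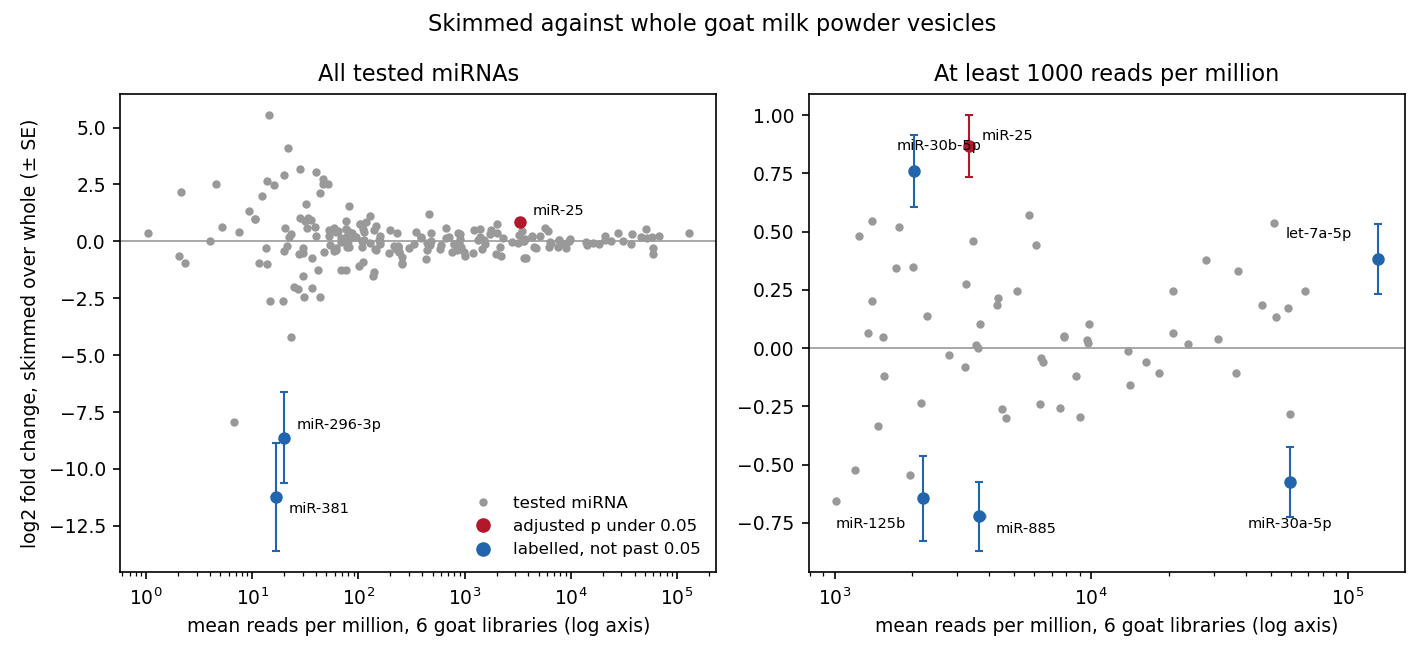
Log2 fold change of skimmed over whole powder (bars on labelled miRNAs: SE) against the mean CPM of the 6 goat libraries (log axis), for all 209 tested miRNAs on the left and for the 64 with at least 1000 CPM on the right. Only miR-25 passed an adjusted p of 0.05 in the edgeR test plotted (DESeq2's Wald test called 22), and the fold changes spread widely below 100 CPM.

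The spread between libraries set what could be seen. The median SE of the log2 fold change was 0.15 for the 64 miRNAs with at least 1000 CPM and 0.24 for the 126 with at least 100 CPM. Low miRNAs were close to all-or-none. Of the 364 miRNAs, 123 had at least 100 reads in one goat library and at most 10 in another, and 58 of these were among the 209 tested. Each goat library held 10 to 22 miRNAs with 11 to 99 reads but 61 to 81 with at least 100 and under 1000 reads. In counts simulated with the spread of these libraries, a 2-fold change was recovered for 74.4% of changed miRNAs with at least 1000 CPM and for 3.2% of those below. The simulation drew each miRNA from a single smooth distribution and was not made to copy the all-or-none pattern. Recovery of low miRNAs in the data may therefore differ.

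**Figure D3:**
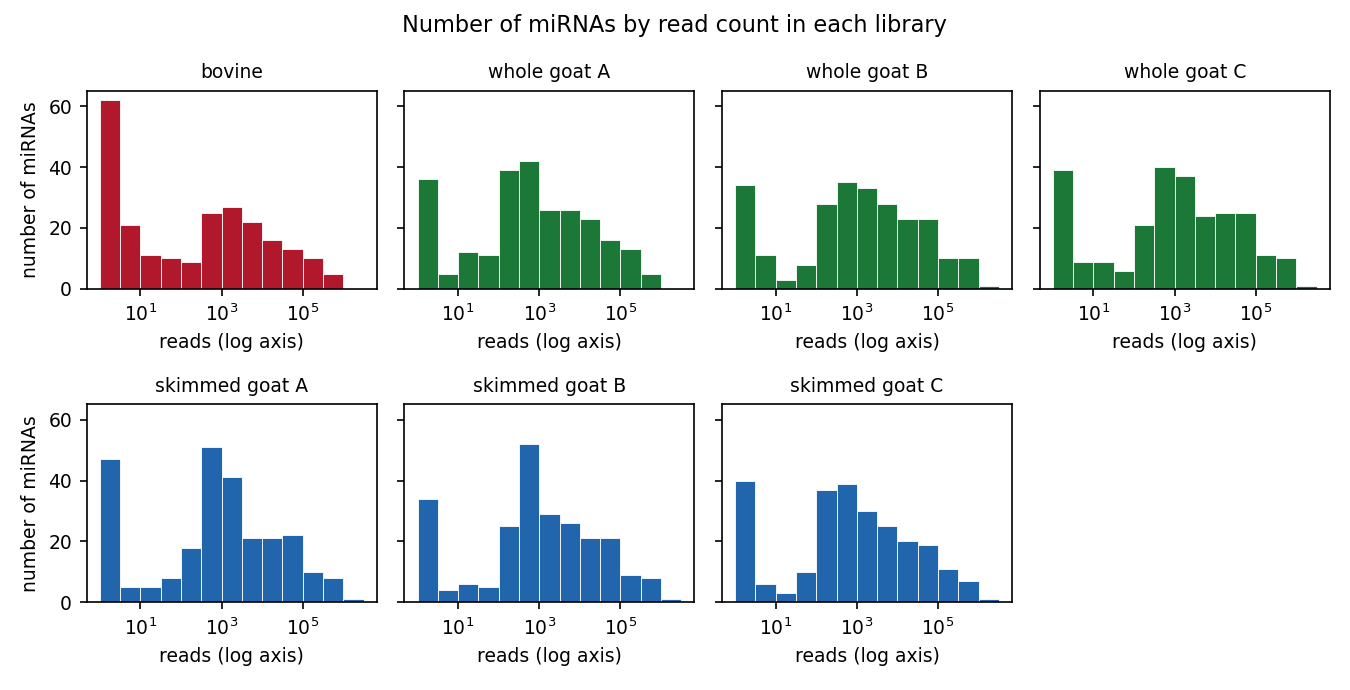
Number of miRNAs (vertical axis) by estimated reads per miRNA (horizontal log axis) in each of the 7 libraries. In every goat library, miRNAs with 11 to 99 reads were fewer than those with 1 to 10 reads or with at least 100 and under 1000 reads.

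Families and groups of miRNAs were then compared between the goat powders as 11 lists. None passed a test of a shift one way, with camera at a preset correlation (lowest adjusted p = 0.16; 1 list at an unadjusted p under 0.05) or with fry (lowest adjusted p = 0.34; 1 list at an unadjusted p under 0.05). In fry's test of change in either direction, taken up as a result after its values were seen, 7 lists had an unadjusted p under 0.05 and 5 passed after adjustment: the leukocyte list (adjusted p = 0.00043), the milk vesicle list, the miR-30 family and the imprinted cluster (0.016 each), and the stromal and endothelial list (0.020). Of these 5 calls, only the imprinted cluster's held without whole A (0.072 for each of the others), only those of the leukocyte and milk vesicle lists without whole B (0.062 to 0.065 for the others), only the leukocyte list's without skimmed B (0.088 to 0.13 for the others), and all but the leukocyte list's (0.12) without skimmed A. Over miRNAs with a mean of at least 100 CPM, which leaves out all-or-none members such as miR-150, the calls of the leukocyte list (0.19), the imprinted cluster (0.38) and the stromal and endothelial list (0.052) were lost and those of the miR-30 family and the milk vesicle list held (0.016 each). Counts of members are those of edgeR unless DESeq2 is named. The let-7 and miR-98 family came first. It held 25.9% ± 2.16 of whole and 30.8% ± 3.17 of skimmed miRNA reads (SD, n = 3), and 8 of its 10 tested members had values above 0, among them let-7a-5p (log2 fold change 0.38 ± 0.15 SE) and let-7b (0.54 ± 0.23). No member passed the threshold in edgeR, DESeq2's Wald test called let-7a-5p (adjusted p = 0.048), and the list had a camera p of 0.014 before and 0.16 after adjustment, with an adjusted p = 0.85 with an estimated correlation. Leaving out skimmed library C brought it past the threshold at the preset correlation (adjusted p = 0.039), but not with an estimated correlation (adjusted p = 0.97). The miR-30 family took 15.1% ± 0.417 of whole and 12.7% ± 0.289 of skimmed reads. Its members went both ways, with miR-30a-5p lower and miR-30b-5p and miR-30c higher in skimmed, and these 3 of its 6 tested members passed when adjusted over the list alone, although 0 passed over all miRNAs in edgeR. DESeq2's Wald test called the same 3 over all miRNAs. Its median was -0.06 and its mean 0.06. The shares of both families did not overlap between the powders, nor did those of the epithelial and the stromal and endothelial lists, 4 of the 11 lists (exact permutation p = 0.1 each, the smallest possible; 0.28 adjusted over the 11 lists).

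In the list of miRNAs often reported as abundant in milk vesicles, miR-25 rose and the other 31 tested members did not pass in edgeR, while DESeq2's Wald test called 4 members, miR-25, let-7a-5p and miR-151-3p higher and miR-30a-5p lower. Adjusted over the list alone 5 passed, namely miR-25, miR-151-3p and miR-143 higher and miR-30a-5p and miR-141 lower in skimmed. This list held 71.4% ± 0.577 of whole and 72.2% ± 0.848 of skimmed reads. The miR-17-92 cluster and its paralogs had miR-25 as the 1 member that rose among 10, over all miRNAs and adjusted over the list alone, while miR-92a, its most abundant member, stood at 24600 ± 6062 CPM in whole and 23177 ± 3413 CPM in skimmed. Epithelial miRNAs took 10.6% ± 0.297 and 11.3% ± 0.412 of reads, and 0 of 11 passed in either way of counting. Here miR-200c, miR-200b and miR-375 (a miRNA of secretory epithelia) were the most abundant, and miR-200b stood at 31822 ± 1676 and 30627 ± 628 CPM. Lipid metabolism miRNAs (18 tested), muscle, liver and nerve miRNAs (4 tested), erythroid miRNAs (3 tested) and miRNAs of the imprinted DLK1-DIO3 cluster (24 tested) also had 0 members past the threshold in either count in edgeR. DESeq2's Wald test called 3 members of the imprinted cluster list as fixed, miR-381 and miR-432 lower and miR-154b higher in skimmed (532, 807 and 1 reads in the skimmed libraries). It called 0 of the epithelial, lipid metabolism, erythroid and muscle, liver and nerve lists. The imprinted cluster list names miR-411a but not miR-411b, which DESeq2's Wald test also called lower in skimmed (adjusted p = 0.0055). Names outside the list, such as miR-411b, miR-411c and miR-409b, are in none of its counts. The most abundant members were miR-148a and miR-23a in the lipid list, miR-128 at 659 ± 224 and 691 ± 10.6 CPM in that of other tissues, and miR-411a, miR-379 and miR-494 in the imprinted cluster list.

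Markers of other cell types that milk may hold were measured in both goat powders. Leukocyte miRNAs took 2.83% ± 0.291 of whole and 2.80% ± 0.105 of skimmed reads, most of it miR-146b, at 21103 ± 2130 and 20677 ± 1213 CPM. None of their 9 tested members passed over all miRNAs in edgeR, DESeq2's Wald test called miR-150 (adjusted p = 0.029), and 2 passed when adjusted over the list alone, with miR-223 higher and miR-150 lower in skimmed. Lymphoid miR-150 had 117, 74 and 187 reads in whole and 0, 1 and 0 in skimmed. Stromal and endothelial miRNAs took 0.971% ± 0.103 and 0.787% ± 0.0285 of reads, with 5 of 6 values below 0. Of these, 0 passed over all miRNAs in edgeR and 2 over the list alone, with miR-125b lower (2766 ± 672 against 1651 ± 222 CPM) and miR-143 higher (1510 ± 36.7 against 2038 ± 387 CPM) in skimmed. DESeq2's Wald test called 2 members, miR-125b lower (adjusted p = 0.029) and miR-126-3p higher (0.029), the latter with 188, 361 and 0 reads in the skimmed libraries and 0 in each whole library. The lists differ in sign between their measures: the leukocyte list had a median log2 fold change of 0.01, a mean of -0.81 and a camera direction below 0, the imprinted cluster a median of 0.20, a mean of -0.34 and a camera direction below 0, and the erythroid list a median of 0.03 with a camera direction below 0. The miR-30 family had a camera direction above 0.

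The bovine powder served as a second kind of milk powder, with a single library, so that species, product and library cannot be separated and no test was made. Its leading miRNAs were largely those of the goat powders: 8 of its 10 most abundant miRNAs were among the goat 10. Let-7a-5p came first, at 132424 CPM (95% Poisson interval 132125 to 132724) against 130577 ± 18560 CPM (SD, n = 6) in the goat libraries. Within the let-7 family the balance differed, since let-7b reached 115600 CPM against 51352 ± 13862 CPM in goat, while let-7f stood at 24602 CPM against 67844 ± 4766 CPM and let-7i at 514 CPM against 5153 ± 633 CPM. Other leading miRNAs above every goat library were miR-30a-5p (90679 CPM), miR-30d (76585 CPM), miR-92a (58611 CPM against 23888 ± 4469 CPM) and miR-200c (55374 CPM), and miR-200b, at 32904 CPM (32754.5 to 33053), lay within its counting interval of the highest goat library, at 32884.5 CPM. Below every goat library lay miR-26a and miR-148a, the latter at 28332 CPM against 52288 ± 9324 CPM. Bovine miR-21-5p, at 52140 CPM, lay within the goat range.

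Among 125 miRNAs with a mean of at least 100 CPM over the 7 libraries, the bovine library lay above every goat library for 35 and below every goat library for 68, where chance would put 14.3% on each side. That mean weighs 6 goat libraries against 1 bovine library, so a bovine-high miRNA needs a far higher CPM to enter than a goat-high one. For example, miR-11976, at 420 CPM in bovine and at most 0.457 CPM in goat, was left out. How the miRNAs divide between above and below thus partly reflects this filter. At least 4-fold outside the goat range were 36 miRNAs, 2 of them above and 34 below. All counts in this comparison are of names, and rows that share reads were not summed for it. Among those below, miR-3613a and miR-3613b had the same value in every library, as did miR-382 and miR-3578, so distinct miRNAs were fewer. The 2 above were miR-2285t, of a large ruminant miRNA family, at 1475 CPM (1443 to 1507) against 1.03 ± 0.554 CPM in goat, 856-fold above the highest goat library, and miR-196a, at 648 CPM and 6.99-fold above it. They were followed by miR-193a-5p (3.62-fold above the highest goat library), miR-532 (3.16-fold) and miR-320a (18289 CPM, 3.12-fold). How goat reads that differ from the bovine sequences were treated is not given, so a goat value near 0 need not mean absence in goat. Farthest below the goat range was miR-155, a miRNA of activated immune cells, at 7.75 CPM (5.63 to 10.4) against 1403 ± 188 CPM, 149-fold below the lowest goat library. Next came miR-374a (123-fold below the lowest goat library), miR-409b (105-fold), miR-224 (104-fold) and miR-223 (101-fold). The bovine reads of these 5 miRNAs came to between 0.0577% and 0.0873% of the reads the 6 goat libraries held together.

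**Figure D4:**
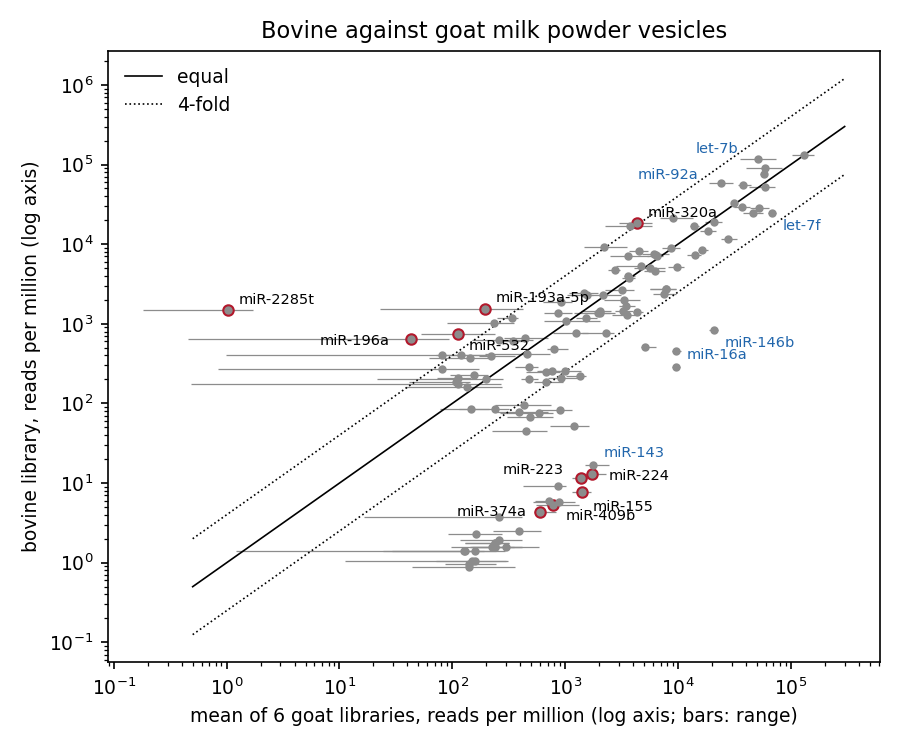
CPM in the bovine library against the mean CPM of the 6 goat libraries (both log axes; horizontal bars: goat range) for 125 miRNAs with a mean of at least 100 CPM; red circles are the 5 miRNAs farthest above and the 5 farthest below the goat range. A separate group of miRNAs, with miR-155 and miR-143 among them, lay about parallel to the line of equality and far below it.

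By list, the bovine library held less of the immune and imprinted groups and as much of the epithelial one. Leukocyte miRNAs took 0.288% of bovine reads (exact binomial 95% interval 0.284 to 0.293), against 2.83% in whole and 2.80% in skimmed goat powder. Besides miR-155 and miR-223 this group holds miR-146b, at 828 bovine CPM against 20890 ± 1568 CPM in goat. Its member with the most bovine reads, miR-342, fell less, at 1287 CPM against 3545 ± 729 CPM. Its member miR-29b went the other way, at 372 bovine CPM against 143 ± 47.8 CPM. The list of the imprinted DLK1-DIO3 cluster took 0.0101% (0.00925 to 0.0109) against 0.463% in whole and 0.461% in skimmed goat. The bovine reads of its members miR-411a, miR-379 and miR-494 came to 0.0702%, 0.113% and 0.0868% of the pooled goat reads. Its member with the most bovine reads, miR-487b, had 380, at 1.45% of the pooled goat reads. Erythroid miRNAs took 0.0284% (0.0270 to 0.0298) against 0.985% and 0.947%, nearly all of it miR-16b, which many cell types express. The row of miR-16b shares reads with that of miR-16a, which is not in this list. In the bovine library miR-16a had 2597.5 reads and miR-16b 1608, and over the 7 libraries their log2 ratio ran from 0.0002 to 0.69. The size of the fall in this list is therefore uncertain. Lipid metabolism miRNAs stood at 5.50% (5.48 to 5.52) in bovine and 11.8% and 11.3% in goat, and muscle, liver and nerve miRNAs at 0.0248% (0.0235 to 0.0261) against 0.0832% and 0.0920%. Epithelial miRNAs made up 11.2% (11.2 to 11.3), within the range of the goat means of 10.6% and 11.3%. Higher shares in the bovine library were seen for the miR-30 family (20.02%; 19.99 to 20.05), the miR-17-92 cluster and paralogs (6.11%; 6.09 to 6.13, most of it miR-92a), stromal and endothelial miRNAs (1.75%; 1.74 to 1.76, led by miR-125b) and the list of milk vesicle miRNAs (79.5%; 79.4 to 79.5). The let-7 and miR-98 family took 29.4% (29.3 to 29.4), between the means of whole and skimmed goat powder. In all, 123 miRNAs had at least 10 reads in each of the 7 libraries. Some passed in the bovine library with few reads, such as miR-3613a with 10 and miR-369-3p with 11. These came to 0.0790% and 0.0764% of the pooled goat reads, a share for which carry-over between libraries stays open. The bovine library held 148 miRNAs with at least 10 reads, against 202 to 213 in the goat libraries.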

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

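The alternatives that sum rows sharing reads, divide reads by reads per template molecule or use fry in either direction were chosen after seeing the data. Where edgeR called 1 miRNA in skimmed against whole powder, it called 0 with DESeq2 size factors, with library totals only, with upper-quartile scaling or without let-7a-5p, 2 with no filter (miR-25 and miR-885), 4 over miRNAs with a mean of at least 100 CPM (also miR-30b-5p and miR-30a-5p), 2 with read-sharing rows summed (miR-25 and miR-30b-5p), 5 with reads divided by reads per template molecule (those 4 and miR-125a) and 3 at an adjusted p under 0.10. It called 1 after thinning, limma-voom called 1, and DESeq2's Wald test called 22 of 243, of which 13 were all-or-none miRNAs and 9 were not. Leaving out 1 library gave 0 to 1 calls, with the call kept only without skimmed A. The 100 CPM minimum tests fewer miRNAs (126) and leave-one-out fits use fewer libraries, and for the other alternatives the cause was not tested. Upper-quartile scaling moved the median log2 fold change of the 209 miRNAs from 0.03 to -0.11 and the share above 0 from 54.1% to 42.6%.

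With the letter as a replicate block, edgeR called 0 miRNAs (miR-25 adjusted p = 0.11) and camera 0 lists. In fry's test of either direction 5 lists were called with the block. The imprinted cluster was no longer among them (adjusted p = 0.14), and the epithelial list was (0.024). The letters were not taken as pairs, since nothing in the labels says that they mark a shared batch. Deviations of same-letter libraries from their group means correlated across the 209 miRNAs at 0.20 for A, 0.14 for B and 0.06 for C. No value for libraries of different letters is given beside them, so these correlations do not decide whether the letters pair the libraries.

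The number of lists called for a shift one way was 0 under all alternatives except leaving out 1 library, which gave 0 to 1 (the let-7 and miR-98 family without skimmed C, with an adjusted p = 0.97 at an estimated correlation). With fry in either direction 5 lists were called, and 1 to 6 with 1 library left out (1 without whole A or skimmed B, 3 without whole B), 2 with reads per template molecule (the miR-30 family and the milk vesicle list), 3 over miRNAs with a mean of at least 100 CPM (those 2 and the miR-17-92 cluster and paralogs) and 4 to 6 under the other alternatives run. The lists called by fry in either direction were not always the same ones. With no filter the stromal and endothelial list was lost (fry adjusted p = 0.0504), and without let-7a-5p the epithelial list was added (0.047). The replicate block exchanged the imprinted cluster for the epithelial list. The difference in detected miRNAs, -2.32 for skimmed minus whole, ranged from -6.26 to 2.18 when 1 library was left out. The number of miRNAs with the bovine library outside the goat range was 36 at 4-fold, 58 at 2-fold, and 68 at 4-fold over miRNAs with a mean of at least 10 CPM. Of 724 values of named miRNAs under alternatives, 648 kept their direction and side of the threshold, 17 came past it, 10 lost it and 49 turned sign.

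All sign changes were in log2 fold changes near 0 that passed no threshold in the main edgeR test. Another scaling shifts all miRNAs about alike, and the sign changes under the scalings followed such a shift: with upper-quartile scaling the miRNAs that changed sign shifted by -0.15 to -0.14 (median of the 209, -0.15), with library totals by -0.10 to -0.09 (-0.09), with DESeq2 size factors by -0.04 to -0.03 (-0.03), in the DESeq2 Wald test, which uses those factors, by -0.05 to -0.03 (-0.04), and with no filter, which also moves the scaling, by -0.07 to -0.06 (-0.06). They say nothing of single miRNAs, and the cause of the others was not tested. With upper-quartile scaling the values were -0.0098 for miR-148a, -0.11 for miR-200b, -0.12 for miR-16a, -0.089 for miR-146b, -0.14 for miR-342, -0.11 for miR-16b and -0.13 for miR-92a. With library totals only they were -0.055 for miR-200b, -0.066 for miR-16a, -0.029 for miR-146b, -0.093 for miR-342, -0.056 for miR-16b and -0.086 for miR-92a. With no filter they were -0.025 for miR-200b, -0.039 for miR-16a, -0.055 for miR-342, -0.028 for miR-16b and -0.048 for miR-92a. With reads per template molecule they were -0.0027 for miR-200b, -0.0078 for miR-16a, -0.070 for miR-342 and -0.037 for miR-92a. In the DESeq2 Wald test they were -0.0015 for miR-200b, -0.011 for miR-16a, -0.034 for miR-342, -0.00044 for miR-16b and -0.028 for miR-92a. With DESeq2 size factors they were -0.0051 for miR-16a, -0.029 for miR-342 and -0.023 for miR-92a, with the 100 CPM minimum -0.011 for miR-342 and -0.0048 for miR-92a, and with the replicate block -0.0048 for miR-342. Leaving out 1 library gave -0.014 to 0.077 for miR-200b, -0.057 to 0.079 for miR-16a, -0.24 to 0.17 for miR-342, -0.046 to 0.089 for miR-16b, -0.088 to 0.43 for miR-128, -0.56 to 0.37 for miR-499, -0.17 to 0.18 for miR-92a, -0.62 to 0.18 for miR-93 and -0.44 to 0.17 for miR-411a.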

Other observations

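The miR-2284 and miR-2285 family, a large group of miRNAs named in ruminants, was not among the lists and was chosen after its values were seen. Its 59 names held 2008 CPM in the bovine library and 134 to 303 CPM in the 6 goat libraries. Most of the bovine reads were those of miR-2285t, at 1475 CPM against 1.03 ± 0.554 CPM in goat (SD, n = 6). Next came miR-2285ba, at 186 bovine CPM against 0.119 ± 0.0708 CPM, and miR-2284x, which goat libraries also held, at 185 bovine CPM against 108 ± 37.6 CPM. Reads of this family could be split between near-identical names, so the values of single members are uncertain, and no bovine value has a replicate. All names are bovine, and how goat reads that differ from the bovine sequences were treated is not given. Low goat values under these names therefore need not mean that goat forms of the family were absent.

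The test of carry-over between libraries was chosen after the result was seen. The fry test in either direction was also taken up after its values were seen, though its count over splits was set before those splits were run. Many low miRNAs were all-or-none in the goat libraries: 123 had at least 100 reads in one library and at most 10 in another, such as miR-381 and miR-150. For these 123 miRNAs, read-counting error predicts 0.00102 times the observed number of low values (0.431 against 424). They were picked for holding both high and low values, so a low ratio was built in and it is no independent test. A difference between the powders is argued against as the whole cause. Libraries of the same powder disagreed on 43 to 55 miRNAs and those of different powders on 44 to 60. The lowest number within a powder over the highest between powders was 0.717. A candidate explanation is that few template molecules were each copied into many reads. The variance between libraries of a powder then grows with about the first power of the mean, and the measured power over 103 miRNAs was 1.18 (95% bootstrap interval 1.03 to 1.33, 2000 resamples). That interval lies above the first power, and the fit left out the lowest and highest means. Variance over mean was not constant, rising from 271 to 368 across the fitted range of means and standing at 931 above it. The 40 miRNAs with at least 100 reads in exactly 1 goat library and at most 10 in every other goat library had a median of 288.5 reads there.

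Some abundant goat miRNAs were seen in the bovine library at a narrow low share. Of 104 miRNAs with at least 10000 pooled goat reads, none had bovine reads under 0.0539% of the pooled goat reads, and 18, picked as those under 0.2%, had 0.0539% to 0.143% (median 0.0765%), among them miR-155, miR-223, miR-143 and miR-411a, and the next share was 0.309% for miR-16b. In the other direction, 4 miRNAs, picked as those with at least 1000 bovine reads and at most 20 reads in each goat library, namely miR-2285t, miR-11976, miR-215 and miR-2285ba, had goat means at 0.0554% to 0.129% of the bovine reads (median 0.104%). The medians differed by a factor of 1.36, but both sets were picked for a low share, so this ratio does not decide whether reads were carried over between libraries. Carry-over stays open, as do species and product, which were not tested.

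The bovine library held fewer miRNAs with at least 10 reads, 148 against 202 to 213 in goat. Its lower depth is argued against as the whole cause, since the goat library with the fewest at the bovine depth still held 1.35 times as many. Species, product, library and a smaller number of template molecules stay open and were not tested with a single library.

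For the comparison of skimmed with whole powder, the 10 splits of the 6 goat libraries into groups of 3 are too few for a share under 0.05. The real split gave 1 called miRNA and the highest other split 0, so 1 split gave as many. For lists tested for a shift one way the real split gave 0 and the highest other split 1, so all 10 gave as many. For lists tested with fry in either direction the real split gave 5 and the highest other split 1, so 1 split gave as many.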
